A study of Mus musculus with 77 samples.

How the data were processed

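The array values were read as deposited, as a linear intensity per numbered transcript cluster in 6 samples (3 of microglia and 3 of splenic monocytes). The authors' summarisation, background correction and scaling are not stated, and the genome build mm9 is named in the submitters' processing notes. Log2 of the intensity was tested without further normalization. No table of gene names for the clusters was used here, so the array gene lists and the planned comparison of the array with the panel were not run.

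The immune-set columns of both NanoString assays hold a deposited signal, which is a count multiplied by a factor of each sample. In 18 of 25 mRNA columns and in all 24 miRNA columns the low values were whole multiples of a single step. Dividing by that step gave 96% to 100% whole values for mRNA and 94.9% to 100% for miRNA, within a tolerance of 0.1 counts. In the other 7 mRNA columns no step was recovered, and gut and red pulp macrophages showed no regular spacing at all. The CNS-set columns hold a deposited score, which is a scaled count rounded to a whole number with regular gaps between values, and so no raw count. Their depth was estimated from the largest step of at least 2 units whose rounded multiples held nearly all values up to 200. How the authors normalized the NanoString values is not stated. The geometric mean of 6 reference genes (Gapdh, Hprt1, Gusb, Cltc, Tubb5 and Pgk1) was 387.538 to 387.544 in the mRNA immune set and 125.785 to 127.355 in the mRNA CNS set, which shows a scaling to these genes. The miRNA assay had no such constant that was found.

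Each NanoString set was fitted apart with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), on log2 of the value plus 10, with all groups of at least 2 samples in 1 model. Features needed a mean of at least 20 in 1 or more fitted groups. The 33 viral probes and 4 mRNA control probes of the miRNA assay were not tested. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1. Differences are microglia minus the other group. Because 10 was added first, differences from groups near the background are compressed. CNS and immune sets were never tested together. The immune sets held 7 microglia, 7 organ macrophage, 4 monocyte and 4 lymphocyte samples, and groups of 1 sample (neutrophils, dendritic cells and, for mRNA, CD11b macrophages without Ly6C) entered no fit. In the immune sets each sample of a group is another source or cell type, so p-values measure the spread between these. In the CNS sets the pairs are not stated to be separate animals. The array labels describe biological triplicates.

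Features higher in microglia than in every other group were the intersection of the calls. Complete separation counted features whose lowest microglia value lay above the highest of all other samples of the set. Single microglia sources were compared with the median of the 7 without a test. Values in the text are means with SD and n, and log2 differences with SE. Totals of recovered counts give the depth, and a floor of 3 counts marks what a sample can show. Steps and floors cover counting error only.

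The groups, tests, thresholds, gene lists, named-gene rule and most other settings were fixed before the data were examined. The design foresaw edgeR for raw counts and limma for linear normalized values, and the second case applied. There were 23 mRNA lists, 18 of them with a measured member, and 15 miRNA lists. They covered microglia, other myeloid and lymphoid cells, neural and organ cell types, and pathways such as TGF-beta, complement, lysosome and immediate early genes. Calls in a list were also counted when adjusted over the list alone. The rule named, among called features without overlap, the 12 largest rises and 12 largest falls on the array and 8 and 8 per NanoString comparison. It also named 15 features each of the intersection and of complete separation, 4 per source, up to 4 called members of each list, members called against their list's majority, every member of short lists, 8 microglial genes and the 4 miRNAs that the study names. The text describes part of these, and 2 genes named by the rule are not reported here.

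The fits were tested on simulated data with differences of 2 and 4 log2 units. The shares describe these data only, and real errors of depth and scaling may worsen them. On the array 94% and 100% were recovered with the right sign (0 false of 194 calls). The CNS sets against astrocytes gave 82.8% and 97.9% for mRNA (1 of 170) and 57% and 98% for miRNA (5 of 160). The immune sets against organ macrophages gave 61% and 95% (5 of 161) and for miRNA 72.3% and 98.2% (0 of 89).

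Other settings, fixed in advance, were pseudocounts of 1 and 50, no low filter and a filter at 100, equal totals, equal upper quartiles, size factors from the median of ratios, the listed housekeeping genes or the total of the top 100 miRNAs, no fold minimum, only the compared pair of groups in the fit, sample weights, replicate blocks and leaving out each sample. Chosen after seeing the data were a scaling to 4 reference genes without Tubb5 and Cltc, a common floor of 3 counts, leaving out the samples in which 1 count was worth over 20, edgeR 4.0.16 (quasi-likelihood) on the recovered counts, and only miRNAs above the mean of the viral probes plus 2 SD. The common floor was 3 counts of the fitted sample whose count was worth most. It stood at 308 units for mRNA and 25.6 for miRNA and was applied to every sample. With edgeR on recovered counts, 88, 287 and 216 mRNAs and 21, 27 and 45 miRNAs were called against organ macrophages, monocytes and lymphocytes.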

Results

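The series profiled sorted mouse microglia, the resident macrophages of the brain and spinal cord, beside other cells of the nervous and immune systems in 77 samples. An exon array measured 16755 transcript clusters in 6 samples, 3 of adult microglia sorted as CD11b-positive and CD45-low and 3 of splenic CD11b-positive, Ly6C-positive monocytes. Each array sample came from 20 to 30 mice aged 8 to 10 weeks. A custom NanoString panel of 400 mRNAs, which counts molecules by hybridised colour-coded probes, was run on 35 samples, and a NanoString assay of 566 mouse miRNAs on 36. Both assays were run on an immune set and on a set from the central nervous system (CNS set), each with its own microglia. The immune set held microglia of 7 sources (eye, cerebellum, olfactory bulb, spinal cord, cortex, hippocampus and brain), macrophages of 7 organs, 4 samples of CD11b monocytes sorted by Ly6C from spleen and bone marrow, 4 lymphocyte samples and single samples of other cells. The CNS sets held 2 samples each of microglia, astrocytes, oligodendrocytes, cortical neurons and hippocampal neurons, and the miRNA CNS set 2 more of red pulp macrophages. The labels call the astrocytes and oligodendrocytes adult and the neurons primary. Preparation can therefore not be told apart from cell type in the neuron comparisons.

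Depth differed widely between samples. In the mRNA immune set the count steps were recovered in 18 of 25 samples, whose total counts ran from 2293 in neutrophils to 94087 in hippocampus microglia, with a median of 6587.5. A single count was worth 0.652 units in splenic B cells and 103 units in olfactory bulb microglia. In the miRNA immune set the totals ran from 1741 in liver macrophages to 75663 in splenic B cells (median 5566), and 33 viral probes without a mouse target averaged lowest in brain microglia and highest, at 17.1, in liver macrophages. The CNS sets held rounded, scaled values, whose spacing gave estimates of depth. For miRNA a single count was worth about 15.7 units in hippocampal neurons replicate 1, 7.44 in cortical neurons replicate 2 and 2.01 to 4.04 in the other 10 samples, or about 3526 to 19762 counts in total. For mRNA the step was 3.46 in cortical neurons replicate 2 and 2.20 in microglia replicate 2 and too small to estimate in the other 8. Their summed values ran from 33676 in cortical neurons to 147271 in microglia for mRNA and from 31701 to 55239 for miRNA, where the viral probes averaged 28.3 to 79.5. Across features, the correlation of the paired samples of a group was 0.889 to 0.992 in the mRNA CNS set. In the miRNA CNS set it was 0.253 for hippocampal neurons, 0.680 for cortical neurons and 0.772 to 0.872 for the others. Features are not independent replicates in these correlations.

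The array compared microglia with splenic monocytes, to find which transcripts part the resident macrophage from a related cell of the spleen. Of 16755 transcript clusters, 3115 passed the test, 1533 higher and 1582 lower in microglia. Among the clusters that passed, 531 were higher and 736 lower by at least 2 log2 units, and 102 were higher and 199 lower by at least 4. The median difference was 1.60 among those higher and -1.89 among those lower, with a median SE of 0.09. The files pair no gene names with these clusters, and no other table was used here, so the array results stay at the level of clusters. Cluster 6906652 had a mean intensity of 10317 ± 440 in microglia and 65.1 ± 1.78 in monocytes (SD, n = 3 each), a difference of 7.31 ± 0.06 (SE) with a limma adjusted p of 4.48e-09. Cluster 6788410 was higher by 7.03 ± 0.07. Cluster 6907945 was lower in microglia by a log2 difference of -7.13 ± 0.29 (62.2 ± 29.3 against 8174 ± 680; limma adjusted p = 1.05e-06), and cluster 6872010 by -7.03 ± 0.40. In 58.8% of all clusters the 3 microglia and 3 monocyte samples did not overlap, where chance gives 10%. Across clusters, r was 0.989 to 0.995 between microglia samples, 0.996 to 0.997 between monocyte samples and 0.836 to 0.849 between the cell types.

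The mRNA CNS set asked which panel genes part microglia from adult astrocytes, adult oligodendrocytes and primary neurons. Against astrocytes, the complement genes C1qc and C1qb, the fractalkine receptor gene Cx3cr1 and the purinergic receptor gene P2ry12 were higher in microglia. C1qc measured 4558.5 ± 788 in microglia and 8 ± 0 in astrocytes (SD, n = 2 each), a log2 difference of 7.98 ± 0.26 (limma adjusted p = 1.18e-12), and Cx3cr1 3836 ± 334 against 6 ± 1.41 (7.91 ± 0.27). Clu, which encodes the secreted chaperone clusterin, was lower in microglia, at 7.5 ± 2.12 against 7417.5 ± 1794 (-8.71 ± 0.46; limma adjusted p = 1.02e-10). The glutamate transporter gene Slc1a3 (-5.97), the phosphatase gene Ptprz1 (-7.48), the membrane glycoprotein gene Gpm6a (-7.36) and the receptor gene Gpr37l1 (-7.11) were also lower. All 3 astrocyte markers on the panel were lower in microglia, Apoe by -4.93. Of 392 genes tested, 252 passed, 170 higher and 82 lower, and 86.7% of genes had both microglia samples on the same side of both astrocyte samples, where chance gives 33.3%. The split was 135 to 121 with upper quartiles made equal and 137 to 123 with size factors from the median of ratios. Calls on 2 genes rested on single samples, since the colony-stimulating factor gene Csf1 (-1.13) measured -0.95 without microglia replicate 1 and -0.90 without astrocytes replicate 1, and the neurofilament gene Nefl (-1.05) -0.81 without microglia replicate 1 and -0.55 without astrocytes replicate 2.

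Against oligodendrocytes, the transcription factor genes Egr1 and Fos had the largest differences among the genes higher in microglia. Egr1 measured 1968.5 ± 445 against 11.5 ± 3.54 (SD, n = 2 each; 6.52 ± 0.37; limma adjusted p = 3.68e-10) and Fos was higher by 6.27 ± 0.30. Enpp2, the gene of the lipid-producing enzyme autotaxin, was lower in microglia at 17 ± 12.7 against 13613.5 ± 1153 (-9.06 ± 0.33; limma adjusted p = 3.63e-12). Aplp1 (-8.93 ± 0.25), a relative of the amyloid precursor gene, the prostaglandin D synthase gene Ptgds (-7.76 ± 0.26) and the myelin glycoprotein gene Omg (-6.34) were lower too. P2ry12 was at 92 in oligodendrocytes and 4665.5 ± 713 in microglia (5.51 ± 0.27). Of 392 genes 255 passed, 178 higher and 77 lower, with 88.8% of genes not overlapping. The split was 133 to 117 with equal upper quartiles and 138 to 113 with the median of ratios.

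Against cortical neurons, P2ry12 (7.94 ± 0.27) and C1qb (7.92 ± 0.25) were among the genes with the largest rises in microglia. C1qb measured 3149.5 ± 491 in microglia and 3 ± 0 in cortical neurons (SD, n = 2 each; limma adjusted p = 1.36e-12). Gpm6a was lower in microglia, at 10 ± 4.24 against 1305 ± 94.8 (-6.05 ± 0.26; limma adjusted p = 1.78e-11), as were Aplp1 (-4.98), the cell adhesion genes Cntn1 (-4.68) and Ncam1 (-4.65), and Nefl (-2.18). Of 392 genes 244 passed, 183 higher and 61 lower, and 83.4% did not overlap. The split turned to 90 higher and 185 lower with equal totals and 103 and 154 with equal upper quartiles, and stood at 131 and 113 with the median of ratios. The call on Slc1a3 (-1.26) ended without cortical neurons replicate 2 (-0.70) and without microglia replicate 2 (-1.02).

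Against hippocampal neurons, P2ry12 (8.33 ± 0.27), the cathepsin gene Ctss (8.30 ± 0.29) and C1qc (7.99) led the genes higher in microglia. P2ry12 measured 4665.5 ± 713 in microglia and 4.5 ± 0.707 in hippocampal neurons (SD, n = 2 each; limma adjusted p = 9.01e-13). Gpm6a (-6.38 ± 0.26), Gpm6b (-5.68), the synaptic vesicle gene Sv2b (-4.92 ± 0.38; 3.5 ± 2.12 against 419 ± 195) and Nefl (-4.08) were lower in microglia. Of 392 genes 274 passed, 204 higher and 70 lower, and 86.2% did not overlap. The split was 119 to 146 with equal totals, 123 to 137 with equal upper quartiles and 140 to 125 with the median of ratios.

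Most gene lists lay on 1 side in all 4 neural comparisons, and the list counts were the same when adjusted over the list alone. Of 38 homeostatic microglia genes, a list chosen partly on these samples and so not independent evidence, 34 were higher against astrocytes, 34 against oligodendrocytes, 37 against cortical and 37 against hippocampal neurons. limma called 0 of them lower, with 1 lower at an unadjusted p under 0.05 against oligodendrocytes. Of 6 genes of the TGF-beta pathway, 5 were higher in each comparison, among them the receptor genes Tgfbr1 (5.49, 4.29, 5.70 and 5.61, in that order of comparisons) and Tgfbr2 (3.68, 3.05, 4.11 and 3.90) and the ligand gene Tgfb1 (4.41, 3.85, 4.13 and 4.94). All 4 complement genes tested and all 7 macrophage transcription factor genes were higher in each. The zinc-finger gene Sall1 stood at 3.74 against astrocytes and 4.40 against cortical neurons, with 2.72 as its smallest difference over the 4 comparisons. The purinergic and chemotactic receptor list of 9 had 9, 8, 9 and 9 higher, and the lysosome list of 8 had 5, 5, 8 and 8 higher, with the membrane protein gene Scarb2 lower against oligodendrocytes (-1.43). Of 9 genes of phagocytosis and uptake of apoptotic cells, 5, 6, 6 and 7 were higher, while the receptor gene Axl was lower against astrocytes (-2.76). Of 11 cytokine and chemokine genes, 8, 8, 9 and 9 were higher, with Il18 (-2.66) and Csf1 (-1.13) lower against astrocytes and Csf1 (-2.06) lower against oligodendrocytes. Of 7 genes that respond within minutes to stimulation or to tissue dissociation, 7, 6, 6 and 6 were higher.

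Lists with a single measured member, or few, gave these values in the mRNA CNS set. The co-stimulatory gene Cd86, the only member of the MHC class II and antigen presentation list measured, was higher in all 4 comparisons (4.08, 3.67, 3.14 and 3.79). Csf3r of the neutrophil list (4.71, 4.29, 3.75 and 4.30), Blnk of the lymphocyte list (4.49, 3.84, 3.24 and 4.25) and Siglech of the dendritic cell list (5.31, 4.17, 4.03 and 4.95) were higher in microglia throughout. Nefl, the only neuron marker, was 0.25 against oligodendrocytes and did not pass there. The endothelial gene Slco1a4 passed in 0 of 4 comparisons in limma (0.37, -0.38, -0.98 and 0.60), with an unadjusted p under 0.05 in 1, against cortical neurons. Fcnb, the only measured member of the monocyte list, was too low to be tested. The lists for interferon response, cell cycle, organ macrophages, oligodendrocytes and erythroid cells had 0 measured members. Of the 3 astrocyte markers, 2 were lower in microglia than in oligodendrocytes (Clu -5.61 and Apoe -2.94), 2 than in cortical neurons (Clu -4.28 and Slc1a3 -1.26) and 3 than in hippocampal neurons (Clu -5.20, Slc1a3 -2.26 and Apoe -2.03). Of 6 housekeeping genes, Gusb was higher in microglia (2.40, 2.30, 3.10 and 3.71) while Gapdh was lower (-2.22, -1.42, -1.58 and -2.07), as was Pgk1 in all 4 comparisons (-1.95 against astrocytes and -1.61 against cortical neurons). The median of the 6 changed sign with the scaling against astrocytes (-0.40 to 0.63) and oligodendrocytes (-0.80 to 0.22). The median difference of the whole panel was 0.58, 0.77, 0.78 and 1.12 as deposited and 0.23, 0.38, -0.82 and -0.16 with equal totals. Relative to the panel median, the homeostatic list stood 3.74 to 4.06 higher against astrocytes, 3.18 to 3.43 against oligodendrocytes, 3.73 to 3.95 against cortical neurons and 3.83 to 3.98 against hippocampal neurons over the scalings.

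In the mRNA CNS set 138 of 392 genes were higher in microglia than in each of the 4 neural groups and 31 were lower than in each. The 15 with the largest smallest difference included Ctss (4100.5 ± 614 in microglia, highest other group mean 75.5; smallest difference 5.59), P2ry12 (5.51), C1qb (3149.5 and 61.5; 5.46) and Cx3cr1 (3836 ± 334 and 79; 5.43). Tmem119, the gene of a membrane protein of microglia, measured 2099 ± 399 against at most 53.5 (5.04), Olfml3, a secreted glycoprotein gene, 905.5 ± 117 against 18 (5.03), and the receptor gene Gpr34 838 ± 90.5 against 16 (5.03). C1qc, C1qa, P2ry13, Csf1r, Fos and Ccl3 were also among the 15, at 4.75 or more. Simulations without any difference leave almost no calls to share, and in 100 of these 0 genes were higher than in every group. Lists of these lengths drawn independently would share 18.8 higher and 0.448 lower genes, but the 4 comparisons share the same microglia samples. Neither number is a test of the 138. The count was 81 with equal totals and 88 with equal upper quartiles.

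**Figure D1:**
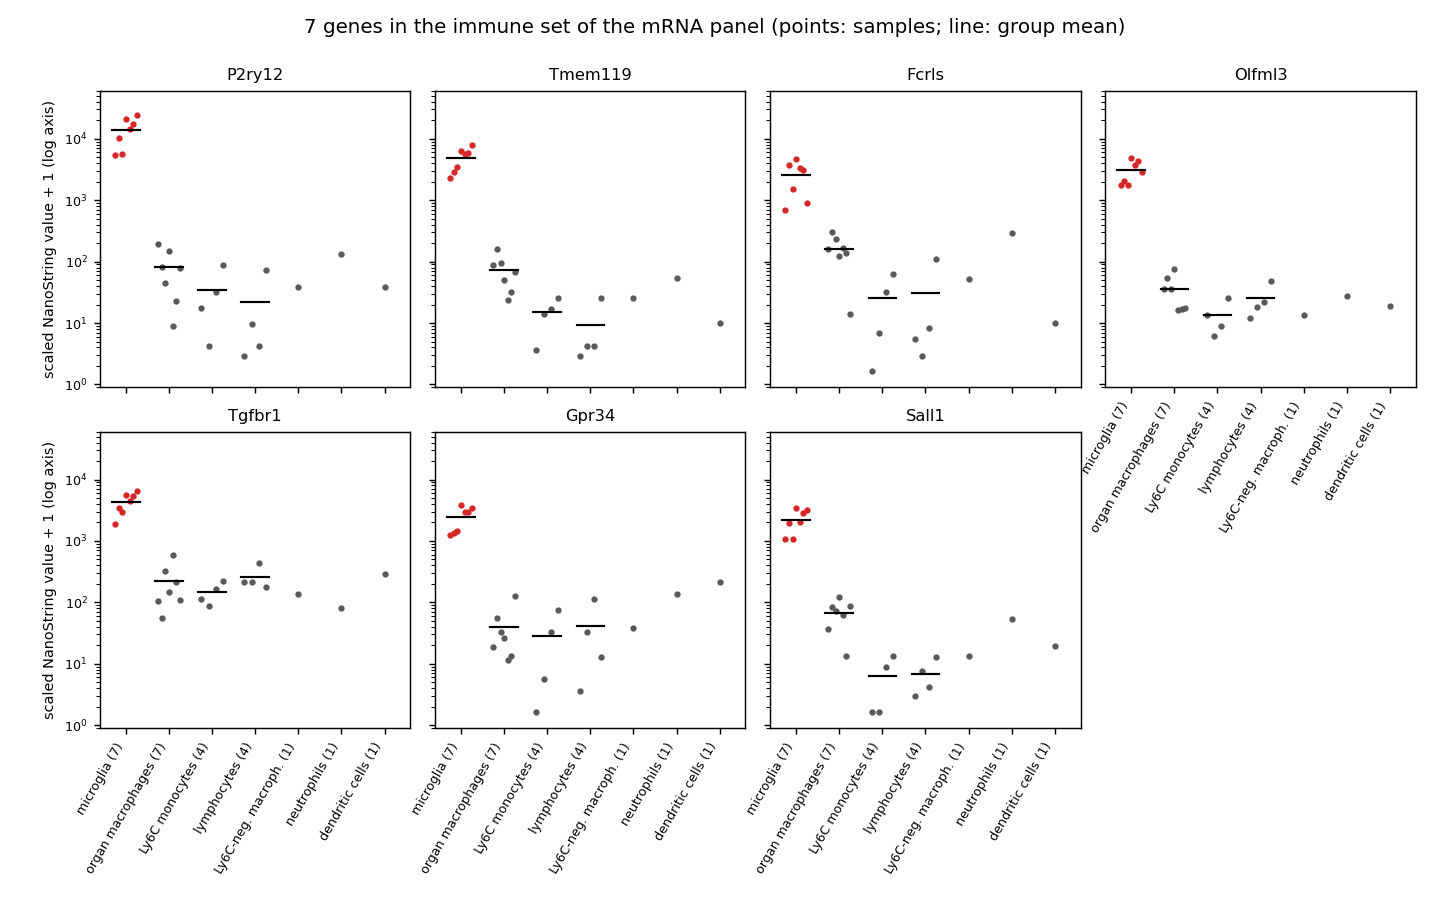
Deposited signal plus 1 of 7 named genes in the 7 groups of the mRNA immune set, on a log axis, with a point per sample and a line at the mean of each group of more than 1 sample. P2ry12, Tmem119 and Olfml3 were higher in all 7 microglia samples than in every other sample, with the lowest P2ry12 value of microglia at 5382 and the highest of other samples at 192.

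The mRNA immune set asked which panel genes part microglia from other macrophages, monocytes and lymphocytes. Against the macrophages of 7 organs, P2ry12 measured 14000 ± 7275 in microglia and 81.9 ± 67.0 in organ macrophages (SD, n = 7 each), a log2 difference of 7.45 ± 0.55 (limma adjusted p = 4.06e-12). Olfml3 (3076 ± 1281 against 35.0 ± 22.3; 6.13 ± 0.38), Tmem119 (4916 ± 2063 against 73.0 ± 47.4; 5.96 ± 0.41), Sall1 (2218 ± 958 against 67.2 ± 35.8; 4.90 ± 0.40) and Siglech (3.80 ± 0.46), a lectin gene, were higher too, and in all 5 of these genes every microglia sample lay above every organ sample. The beta-tubulin gene Tubb5 was lower in microglia at 155 ± 122 against 934 ± 598 (-2.59 ± 0.41; limma adjusted p = 4.45e-06) and its samples did not overlap. The chemokine gene Ccl5 (-3.17 ± 0.92), the complement regulator gene Cfp (-2.63 ± 0.52), Axl (-1.82 ± 0.45) and the chemokine gene Ccl6 (-1.68) were lower as well, with overlap between the groups. Of 400 genes 216 passed, 204 higher and 12 lower, and 28.3% of genes did not overlap, where chance gives 0.0583%. The balance of higher and lower genes followed the scaling, at 40 to 185 with equal totals, 73 to 108 with equal upper quartiles, 85 to 85 with the median of ratios and 126 to 37 with 4 reference genes, while 40 genes were called higher and 12 lower in microglia under the deposited and all 4 of these scalings. With values raised to a common floor of 308 units, 3 counts of olfactory bulb microglia, the calls fell to 85 (84 higher and 1 lower), and with edgeR on recovered counts to 88. The calls on Ccl5 and Axl ended with both, and those on Cfp and Ccl6 with the common floor.

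Against the 4 samples of CD11b monocytes, P2ry12 (8.47 ± 0.64; limma adjusted p = 3.48e-12) and the complement genes C1qc (12000 ± 3609 against 38.5 ± 30.6; 8.15 ± 0.53), C1qa (7.86) and C1qb (7.85) led the genes higher in microglia (n = 7 and 4). Sall1 measured 5.39 ± 5.77 in monocytes (7.12 ± 0.47; limma adjusted p = 2.17e-13), and Tmem119 (7.65) and Olfml3 (7.06) were higher too. Tubb5 (155 ± 122 against 1682 ± 218; -3.63 ± 0.48; limma adjusted p = 1.35e-07), the cytoskeletal gene Gas7 (-3.13 ± 0.66) and Ccl6 (-2.31 ± 0.50) were lower in microglia. Of 400 genes 306 passed, 295 higher and 11 lower, and 56.8% did not overlap, where chance gives 0.606%. The split was 96 to 77 with equal totals, 100 to 84 with equal upper quartiles and 83 to 97 with the median of ratios, and 81 genes were called higher and 11 lower under the deposited and all 4 other scalings. With the common floor 82 were higher and 4 lower, and the calls on Gas7, Fcnb, Cfp, Flot2 (-2.95) and Pgk1 (-1.52) ended. A call that ended there need not rest on few counts, since that floor is many counts in deep samples. Pgk1 in bone marrow Ly6C-low cells held 1136 counts. Calls on 3 named genes ended without single samples, namely the ficolin gene Fcnb (-2.41; -1.48 without bone marrow Ly6C-low cells), the amyloid precursor gene App (-1.14; -1.03 without spleen Ly6C-high cells, spleen Ly6C-low cells or olfactory bulb microglia and -1.12 without bone marrow Ly6C-low cells) and Clu (1.78; 1.09 without eye microglia, 1.65 and 1.60 without bone marrow Ly6C-low and Ly6C-high cells).

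Against the 4 lymphocyte samples, P2ry12 (9.10 ± 0.64), C1qa (8997 ± 2681 against 20.6 ± 26.4; 8.48 ± 0.53; limma adjusted p = 1.00e-13), Csf1r, the gene of the receptor that macrophages need to survive (9128 ± 3034 against 25.8 ± 32.3; 8.34 ± 0.55), and Cx3cr1 (7.80) were higher in microglia (n = 7 and 4). Tubb5 (-2.72 ± 0.48; limma adjusted p = 1.20e-05), the cytoskeletal gene Add1 (353 ± 140 against 975 ± 213; -1.50 ± 0.43) and the Golgi gene Golga3 (-1.35 ± 0.41) were lower. Of 400 genes 275 passed, 261 higher and 14 lower, and 49.8% did not overlap, where chance gives 0.606%. The split was 106 to 96 with equal totals, 138 to 91 with equal upper quartiles, 101 to 118 with the median of ratios and 199 to 56 with 4 reference genes, and 100 genes were called higher and 14 lower under the deposited and all 4 other scalings. With the common floor 79 were higher and 4 lower, and the calls on Ccl5 and Golga3 ended, while edgeR did not call Add1 lower. The fall in Ccl5 (-2.88) rested on the natural killer (NK) cell sample and was -0.86 without it, that in Ahcyl1 (-1.20) was -0.94 without cerebellum microglia, and that in Abi1 (-1.19) was -0.84 without olfactory bulb microglia. Clu (1.68) was 1.00 without eye microglia.

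The panel median stood at 1.12 against organ macrophages, 2.56 against monocytes and 2.16 against lymphocytes as deposited, and moved to -0.98, 0.19 and 0.07 with equal totals, to -0.37, 0.16 and 0.33 with equal upper quartiles and to -0.18, -0.03 and -0.13 with the median of ratios. Gene lists of the immune set were therefore also read relative to it. Of 38 homeostatic genes, again chosen partly on these samples and not independent evidence, 36, 36 and 37 were higher against organ macrophages, monocytes and lymphocytes, and 37, 36 and 37 when adjusted over the list alone. Under other scalings at least 21, 27 and 29 were higher, and the list stood 2.25 to 2.61, 2.35 to 2.77 and 3.05 to 3.46 above the panel median. All 7 transcription factor genes were higher as deposited (Bhlhe41 4.08, 5.47 and 4.60), and at least 3, 5 and 4 in every scaling. Of 5 complement genes 4 were higher in each comparison and at least 3, 4 and 4 in every scaling, while Cfp was lower against organ macrophages (-2.63) and monocytes (-2.10). All 9 purinergic and chemotactic receptor genes were higher as deposited, and at least 4, 6 and 8 in every scaling. All 8 lysosome genes were higher as deposited, among them the cathepsin gene Ctsd against organ macrophages (4.65) and the legumain gene Lgmn against monocytes (5.42), and at least 5, 4 and 4 in every scaling.

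The phagocytosis list of 9 had 6 higher and Axl lower (-1.82) against organ macrophages, 8 higher against monocytes and 9 against lymphocytes, with the integrin gene Itgb5 at 5.14, 6.53 and 7.92. Of 6 TGF-beta pathway genes, 4, 5 and 4 were higher, with Tgfbr1 at 4.49 ± 0.43, 4.78 and 3.97. The median of this list against organ macrophages was 1.53 as deposited and -0.90 with equal totals, 0.08 to 0.41 above the panel median, and Tgfb1 (1.12; 0.99 without brain microglia) and Tgfbr2 (1.94) turned to -1.32 and -0.47 with equal totals. Of 11 cytokine and chemokine genes, 6, 7 and 8 were higher as deposited and Ccl5 and Ccl6, Ccl6, and Ccl5 were lower, with the list median against organ macrophages turning from 1.12 to -1.15 with equal totals. Immediate early genes were higher in 4, 6 and 6 of 7 cases, with Jun at 4.09 and Egr1 at 4.03 against organ macrophages. Fos (1.77) turned to -0.69 there with equal totals and lost its call without red pulp macrophages (1.18), cortex microglia (1.53), hippocampus microglia (1.53), cerebellum microglia (1.57) or olfactory bulb microglia (1.65). Apart from the homeostatic list, the list counts were the same when adjusted over the list alone.

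Of the lists with few members, Slc1a3 was higher in microglia against organ macrophages (3.62), monocytes (4.43) and lymphocytes (4.48). Apoe was -0.85 and 0.55 without passing against organ macrophages and monocytes, negative against monocytes with equal totals, equal upper quartiles, the median of ratios and 4 reference genes (-2.80 to -0.50), and higher against lymphocytes (3.80), while Clu was -0.71 against organ macrophages without passing and its differences of 1.78 and 1.68 from monocytes and lymphocytes turned to -0.10 and -0.14 with the median of ratios. Siglech (3.80, 5.54 and 5.31) and Blnk (2.94, 4.48 and 3.15) were higher throughout. Among lymphocytes, however, B cells held Blnk at 2937 and the other samples at most 47.7, so that 3.15 does not describe B cells. Csf3r was higher against organ macrophages (2.51) and lymphocytes (4.99) and was -0.35 against monocytes. Cd86 was 0.77 against organ macrophages without passing and higher against monocytes (2.13) and lymphocytes (2.49), and turned to -1.62, -0.77 and -0.09 with equal totals. Nefl (-0.11, 1.01 and 1.08) and Slco1a4 (-0.76, 0.98 and 0.95) did not pass, and Fcnb (-0.30 and 0.92) did not pass against organ macrophages and lymphocytes. Among 6 housekeeping genes Gusb (2.00, 2.80 and 2.50) and Hprt1 (1.35, 2.87 and 1.75) were higher as deposited and turned negative under the median of ratios against monocytes (-0.49 and -0.20) and lymphocytes (-0.47 and -1.16), while Tubb5, Pgk1 against monocytes (-1.52) and Cltc against lymphocytes (-1.70) were lower.

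Across all 25 samples of the mRNA immune set, 92 of 400 genes had every microglia sample above every other sample and 1 had every microglia sample below, where chance gives 0.000832. For 45 genes the gap was at least 1 log2 unit. In 10 of the 92 the lowest microglia value held at most 3 counts, in cerebellum or olfactory bulb microglia, and in 3 of these (Cables1, Scamp5 and Rnase4) only 1, so that their separation is not secure. P2ry12 had the widest gap (4.74), between 5382 in eye microglia and 192 in heart macrophages. Olfml3 (4.40; 1762.5 in cerebellum microglia and 73.8 in liver macrophages), Tmem119 (3.72), Itgb5 (3.33), Sall1 (3.01; 1058 and 123), Cx3cr1 (2.64), the cathepsin gene Ctsf (2.54), C1qc (2.49), Gpr34 (2.48), P2ry13 (2.37), Serpine2 (2.30), Usp2 (2.27), Fcgr1 (2.24) and Rps2 (2.20; 4 counts against 3) were also among the 15 with the widest gap. In 10 of the 92 the highest other value held at most 3 counts, among them Olfml3, Ctsf, Usp2 and Rps2, and in 21 its counts are unknown, so these gaps are not exact. The count of separated genes was 13 with equal totals, 28 with equal upper quartiles, 18 with the median of ratios and 48 with 4 reference genes.

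Single sources of microglia stood apart in named genes, with 1 sample each and so no test. Eye microglia had Ptgds at 1991 (6.50 log2 units above the median of the 7 sources), Clu at 1053 (4.60), Sv2b at 486 (4.10) and the thyroxine carrier gene Ttr at 521 (3.83). Brain microglia had lower values of Atf3 (-4.19), Ccl3 (-4.06), Spint1 (-4.04) and Fos (-3.65), and spinal cord microglia of Ccl4 (-2.60). The brain sample also differed from the 6 others in reference genes used for the scaling (Cltc 2816 against 243 to 925, Gapdh 455 against 1065 to 2594), so that separate processing is not excluded as a cause. The largest differences of olfactory bulb microglia (Dfna5, Cfp, Abi1 and Aif1) and of cerebellum microglia (Igf1, Fgfr1, Slfn14 and Tmem47) rested on a few counts each. Cortex microglia differed most in Rgs1, Spsb1, Hspa1a and Adamts16 and hippocampus microglia in Adamts1, Hspa1a, Olfr111 and Trim47.

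**Figure D2:**
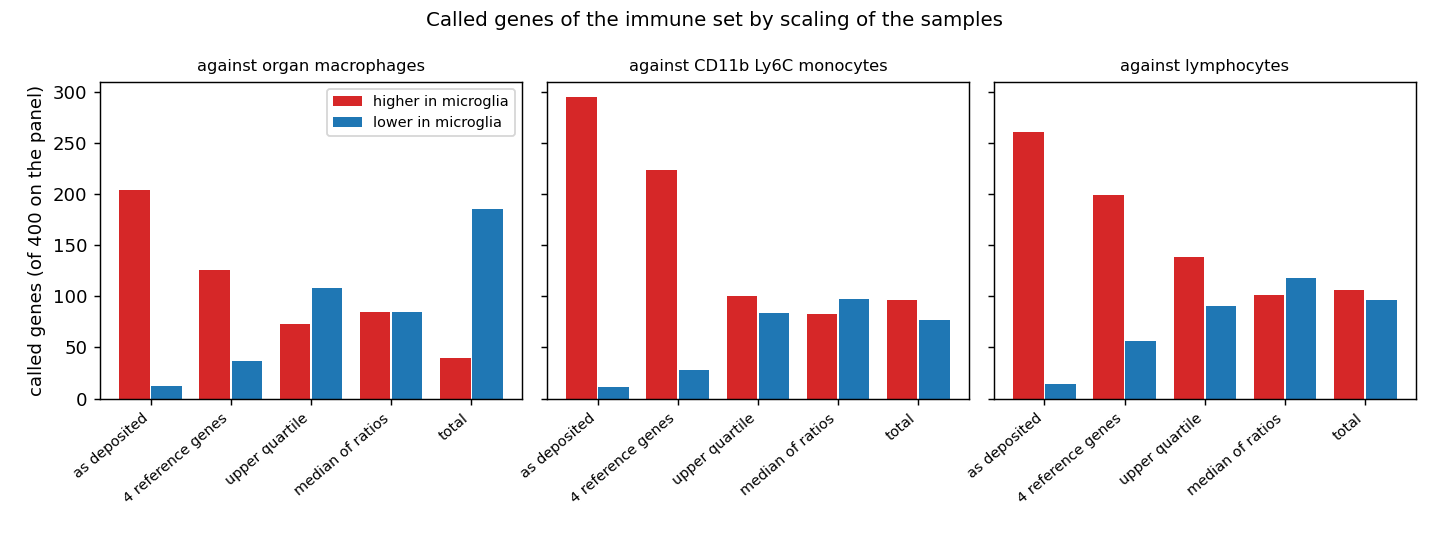
Number of the 400 panel genes called higher (red bars) and lower (blue bars) in microglia against organ macrophages, monocytes and lymphocytes in the mRNA immune set, as deposited and under 4 other scalings of the samples. Against organ macrophages the split turned from 204 higher and 12 lower as deposited to 40 higher and 185 lower with equal totals.

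The miRNA CNS set asked which miRNAs part microglia from neural cells and from red pulp macrophages, the macrophages of the spleen that clear old red cells. miR-342-3p was the miRNA with the most stable difference, at 946.5 ± 65.8 in microglia and 63 ± 15.6 in astrocytes, 42.5 ± 6.36 in oligodendrocytes, 46 ± 12.7 in cortical neurons, 77.5 ± 67.2 in hippocampal neurons and 65.5 ± 4.95 in red pulp macrophages (SD, n = 2 each). The log2 differences were 3.73, 4.19, 4.11, 3.70 and 3.66 (SE 0.53 each), with limma adjusted p from 7.02e-05 to 0.00053. The levels outside microglia all lay below the highest viral probe there (58 to 408 over the samples of the set), so that none of the 5 sizes is exact. The same limit holds for miR-15a and for any level under these probes. The 5 differences passed, and the calls held without each of the 12 samples and under each scaling, while that against hippocampal neurons ended when only those 2 groups were fitted. miR-16 (1151 ± 274 in microglia; 2.18, 2.41, 2.68, 3.61 and 2.50) and miR-15a (419 ± 82.0; 2.54, 2.26, 2.79, 3.34 and 2.68), a pair transcribed from a shared cluster, also passed in all 5 comparisons, so that 3 of 566 miRNAs were higher in microglia than in every other group of this set. The count lower in microglia was 0, since limma called 0 lower than in red pulp macrophages (21 at an unadjusted p under 0.05). Simulations without any difference leave almost no calls to share, and in 100 of these 0 were higher than in every group. Independent lists would share 5.56e-07, but the 5 comparisons share the same microglia samples. Neither number is a test of the 3. Of the 3, only miR-342-3p remained when microglia, oligodendrocytes, red pulp macrophages or astrocytes lost either replicate or cortical neurons lost replicate 1, where the count was 1.

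Against astrocytes 9 of 566 miRNAs passed, 6 higher and 3 lower, and 36.6% of miRNAs did not overlap where chance gives 33.3%. miR-9, abundant in neural cells, was lower in microglia at 20 ± 0 against 1930 ± 1300 (SD, n = 2 each; -5.83 ± 0.97; limma adjusted p = 0.000943), as were the vessel-enriched miR-126-3p (28.5 ± 7.78 against 324.5 ± 98.3; -3.10 ± 0.46; limma adjusted p = 0.000399) and miR-204 (69 ± 18.4 against 664.5 ± 334; -3.02 ± 0.50). The viral probes averaged 37.4 and 38.1 in the microglia samples, so that 20 and 28.5 in microglia are not distinguishable from no signal and the sizes of these 2 differences are not exact. Under the deposited and all 4 other scalings 3 were called higher and 3 lower. miR-125b-5p measured 591 ± 257 against 4298 ± 2828 and did not pass (-2.74 ± 0.76; limma adjusted p = 0.0934). The calls numbered 2 and 4 without astrocytes replicate 1 or 2, 4 and 3 without microglia replicate 1 or 2, and 19 without either replicate of hippocampal neurons. The call on miR-9 ended without astrocytes replicate 1 (-5.09) and that on miR-204 without astrocytes replicate 1 (-2.49) or microglia replicate 2 (-2.78).

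Against oligodendrocytes 10 miRNAs passed, 8 higher and 2 lower, with 40.3% not overlapping. miR-338-3p, known for its high level in oligodendrocytes, was lower in microglia at 94 ± 12.7 against 532 ± 21.2 (-2.39 ± 0.49; limma adjusted p = 0.0122), and miR-29a was higher (362 ± 134 against 32 ± 2.83; 3.10 ± 0.55; limma adjusted p = 0.004). The viral probes averaged 42.8 and 38.4 in the oligodendrocyte samples, so that 32 is not above background and the size of the difference is not exact. Under the deposited and all 4 other scalings 4 were called higher and 2 lower. The count fell to 1 without either oligodendrocyte replicate or microglia replicate 2, to 3 without microglia replicate 1 and to 6 without either replicate of astrocytes or red pulp macrophages, and rose to 19 without either replicate of hippocampal neurons. miR-342-3p was the only named miRNA whose call held without each sample, and miR-338-3p (-2.51 to -2.26) and miR-29a (2.72 to 3.48) lost theirs without either oligodendrocyte replicate and microglia replicate 2.

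Against cortical neurons 16 miRNAs passed, 12 higher and 4 lower, with 45.4% not overlapping. let-7g was higher in microglia at 639 ± 28.3 against 49.5 ± 17.7 (SD, n = 2 each; 3.48 ± 0.51; limma adjusted p = 0.000358), where the viral probes averaged 46.0 and 49.8 in cortical neurons, and held without each sample and under each scaling. Under the deposited and all 4 other scalings 10 of the 12 higher and none of the 4 lower were called by limma. miR-376a, from a miRNA cluster active in neurons, was lower (-3.18 ± 0.81; limma adjusted p = 0.0322), but not called without cortical neurons replicate 1 (-1.90), without either microglia sample (-3.05 and -3.31) or without a sample of astrocytes or red pulp macrophages (-3.18), nor with equal totals, equal upper quartiles or the median of ratios (-2.98 to -2.80 over the scalings). Calls fell to 2 without cortical neurons replicate 1 or microglia replicate 2 and to 6 without cortical neurons replicate 2 or microglia replicate 1, and rose to 42 without either replicate of hippocampal neurons. Against hippocampal neurons 12 passed, 9 higher and 3 lower, with 30.7% not overlapping. miR-16 (3.61 ± 0.52; limma adjusted p = 0.000234) and miR-15a (3.34) were higher and held without each sample, while miR-132, a miRNA induced by neuronal activity, was lower at 67 ± 1.41 against 405.5 ± 196 (-2.35 ± 0.56; limma adjusted p = 0.0286). The call on miR-132 ended without either sample of microglia, red pulp macrophages or astrocytes (-2.37 to -2.33), and with equal totals, equal upper quartiles or the median of ratios (-2.45 to -1.75 over the scalings). Of the hippocampal calls, 6 of the 9 higher and none of the 3 lower held under every scaling. The hippocampal count was 22 without hippocampal neurons replicate 1, 310 without replicate 2 (45 higher and 265 lower), 5 and 3 without microglia replicate 1 or 2, and 6 without either replicate of astrocytes or red pulp macrophages.

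Against red pulp macrophages 11 miRNAs passed in limma, all 11 higher in microglia, with 65.0% of miRNAs not overlapping. At an unadjusted p under 0.05, 20 were higher and 21 lower. Besides miR-342-3p they included let-7g (639 ± 28.3 against 75 ± 8.49; SD, n = 2 each; 2.94 ± 0.51; limma adjusted p = 0.00361) and miR-720 (1412 ± 317 against 90.5 ± 30.4; 3.84 ± 0.76; limma adjusted p = 0.00591), a tRNA fragment once listed as a miRNA. The viral probes averaged 61.6 and 55.5 in red pulp macrophages, with 119 and 129 as the highest, so that 75 and 90.5 are not clearly above background and the sizes are not exact. Under the deposited and all 4 other scalings 7 of the 11 were called. The call on let-7g ended without red pulp macrophages replicate 2 (2.83), and that on miR-720 without either sample of red pulp macrophages or microglia (3.52 to 4.15). The count was 1 and 3 without red pulp macrophages replicate 2 or 1, 3 and 4 without microglia replicate 2 or 1, and 30 without either replicate of hippocampal neurons.

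The miRNA lists of the CNS set held few calls, given here in the order astrocytes, oligodendrocytes, cortical neurons, hippocampal neurons and red pulp macrophages. Of the 4 miRNAs that the study names for microglia, chosen on these samples and so not independent evidence, 1 was higher in each comparison. When adjusted over the list alone 1, 2, 2, 2 and 3 were higher and 2 lower against astrocytes. miR-99a measured -0.64, 1.77, 1.84, 1.69 and 2.15, miR-125b-5p -2.74, 0.85, 1.61, 0.90 and 2.38 and miR-125a-5p -1.47, 0.06, 0.28, -0.94 and 0.65, none of them called over all miRNAs, and the value of miR-125a-5p against oligodendrocytes turned negative with some scalings (-0.24 to 0.12). Of 15 myeloid miRNAs, 2, 2, 3, 2 and 1 were higher and miR-338-3p lower against oligodendrocytes, and when adjusted over the list alone 2, 3, 3, 3 and 4 were higher. Of 14 lymphoid miRNAs, 1, 3, 4, 3 and 4 were higher (1, 3, 5, 4 and 4 when adjusted over the list alone), with miR-30b lower against cortical neurons (-1.89). Of 25 neuron miRNAs, limma called 0 higher and 1, 0, 1, 1 and 0 lower (1, 1, 1, 4 and 0 when adjusted over the list alone; 2, 1, 2, 9 and 1 at an unadjusted p under 0.05, with 0 higher). The astrocyte list of 5 had miR-204 lower against astrocytes and miR-29a higher against oligodendrocytes (3.10), cortical neurons (2.97) and red pulp macrophages (2.66), and adjusted over the list alone also 1 higher against hippocampal neurons. The oligodendrocyte list of 5 had miR-23a higher in 4 comparisons (2.39, 2.28, 2.33 and 2.63) and miR-338-3p lower against oligodendrocytes. Of 9 let-7 members 1 was higher against cortical neurons and 2 against red pulp macrophages, and 1 was lower against astrocytes when adjusted over the list alone. The muscle and heart list of 7, the liver list of 4 and the list of 9 from the miR-17 family clusters had 0 calls in limma. At an unadjusted p under 0.05 the muscle and heart list had 0, the liver list 1 lower against hippocampal neurons, and the miR-17 list 1 higher against astrocytes and 1 against hippocampal neurons. The retina list of 8 had miR-9 and miR-204 lower against astrocytes, the kidney and gut list of 12 miR-204, the lung list of 10 miR-34c higher against hippocampal neurons (3.47; 1.48 without hippocampal neurons replicate 1), the endothelial list of 5 miR-126-3p lower against astrocytes and oligodendrocytes (-1.86), and the erythroid list of 5 miR-16 higher throughout.

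**Figure D3:**
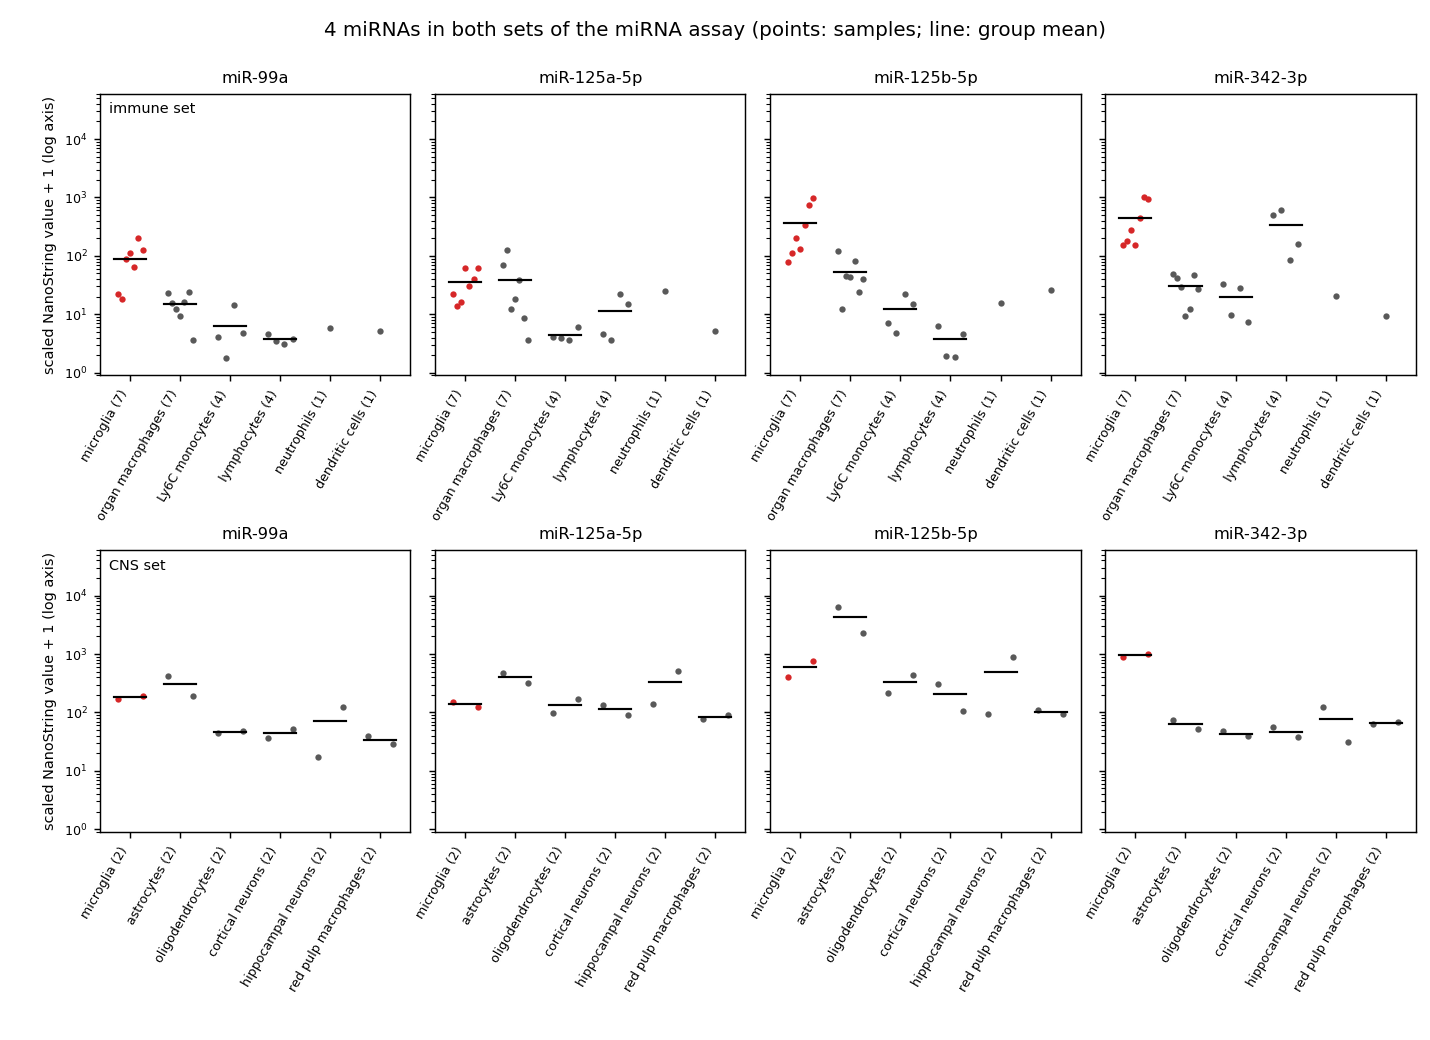
Deposited values plus 1 of 4 named miRNAs in the immune set (top) and the CNS set (bottom), on log axes, with a point per sample and a line at the mean of each group of more than 1 sample. miR-342-3p lay at 946.5 on average in microglia of the CNS set and at 77.5 or less in the other groups, while in the immune set lymphocytes (336) came near microglia (452).

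In the miRNA immune set, microglia were first compared with organ macrophages. miR-342-3p measured 452 ± 372 in microglia and 29.9 ± 16.0 in organ macrophages (SD, n = 7 each; 3.26 ± 0.47; limma adjusted p = 1.36e-05), with no overlap. miR-125b-5p (369 ± 357 against 51.3 ± 36.7; 2.30 ± 0.46; limma adjusted p = 0.00103) and miR-99a (1.79 ± 0.38; limma adjusted p = 0.00152) were higher too. miR-126-3p (4.64 ± 2.54 against 280 ± 292; -3.34 ± 0.57; limma adjusted p = 0.000147) and miR-223, a miRNA of granulocytes and monocytes (28.3 ± 46.6 against 270 ± 312; -2.53 ± 0.71; limma adjusted p = 0.0169), were lower. The viral probes averaged up to 13.7 in these microglia samples, so that 4.64 is not distinguishable from no signal. In this set too, differences from levels under the highest viral probe of the samples (3.06 to 51.2), such as those of miR-99a in organ macrophages (14.0), are not exact in size. miR-342-3p, miR-125b-5p, miR-99a and miR-126-3p were called under every scaling and without each sample, whereas miR-223 lost its call with equal upper quartiles or the median of ratios. Of 105 miRNAs 15 passed, 11 higher and 4 lower, and 0.952% did not overlap, where chance gives 0.0583%. The count was 7 without cortex microglia and 7 without brain microglia. It was 4 (3 higher and 1 lower) with equal upper quartiles or the median of ratios and 9 (5 higher and 4 lower) with the total of the top 100 miRNAs.

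Against CD11b monocytes, miR-342-3p (3.74 ± 0.55), miR-125b-5p (369 ± 357 against 11.4 ± 8.07; 3.68 ± 0.54) and miR-99a (2.44 ± 0.45) were higher in microglia (n = 7 and 4; limma adjusted p = 4.48e-06, 4.48e-06 and 0.000108). miR-223 was lower, at 28.3 ± 46.6 against 4953 ± 4481 (-7.17 ± 0.83; limma adjusted p = 1.88e-07), as were miR-15b (31.7 ± 12.3 against 562 ± 369; -3.59 ± 0.47), miR-148a (4.15 ± 2.60 against 142 ± 93.6; -3.21 ± 0.39) and miR-25 (-2.52 ± 0.42). At 4.15 in microglia miR-148a is not distinguishable from no signal, nor is miR-99a at 5.29 ± 5.58 in monocytes, so these sizes are not exact. These 7 kept their calls under every scaling and without each sample. Of 105 miRNAs 20 passed, 8 higher and 12 lower, and 11.4% did not overlap, where chance gives 0.606%. The count was 13 (3 higher and 10 lower) with equal upper quartiles or the median of ratios and 8 (4 and 4) with the total of the top 100. It was 9 without bone marrow Ly6C-low cells, 11 without bone marrow Ly6C-high cells and 12 without spleen Ly6C-low cells.

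Against lymphocytes, miR-125b-5p (4.37 ± 0.54; limma adjusted p = 2.90e-07), miR-99a (2.64 ± 0.45; limma adjusted p = 5.39e-05) and miR-142-5p (2.42 ± 0.53; limma adjusted p = 0.00132) were higher in microglia (n = 7 and 4). In lymphocytes miR-125b-5p (2.73 ± 2.23) and miR-99a (2.72 ± 0.67) lay below the highest viral probes (3.66 to 6.42), so these 2 sizes are not exact. miR-142-5p averaged 11.8 in lymphocytes and had a median of 148 over the 7 microglia sources. In brain and cortex microglia, the samples with the most counts (32277 and 15643), it measured only 14.4 and 44.6. Depth was not told apart from cell type for this difference. miR-150, a miRNA of mature lymphocytes, was lower, at 6.94 ± 6.36 against 1354 ± 940 (-6.12 ± 0.51; limma adjusted p = 1.01e-10; a size that is not exact, since 6.94 lies within the averages of the viral probes in microglia), as were miR-15b (-3.85 ± 0.47), miR-142-3p (58.8 ± 59.7 against 555 ± 301; -3.40 ± 0.59), miR-21 (-2.84 ± 0.56) and let-7g (364 ± 226 against 1763 ± 451; -2.43 ± 0.57). miR-342-3p measured 336 ± 251 in lymphocytes and did not pass (0.40 ± 0.55; limma adjusted p = 0.584). Of 105 miRNAs 28 passed, 13 higher and 15 lower, and 17.1% did not overlap, where chance gives 0.606%. The count was 16 without B cells and 13 without CD3/CD4 T cells. It was 25 (14 higher and 11 lower) with equal totals, 36 (3 higher and 33 lower) with equal upper quartiles or the median of ratios and 20 (13 higher and 7 lower) with the total of the top 100 miRNAs, and 3 were called higher and 7 lower under all of these. With edgeR on the recovered counts it was 45 (31 higher and 14 lower).

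The 4 miRNAs the study names for microglia, chosen on these samples and not independent evidence, had 3 higher against organ macrophages, 4 against monocytes and 2 against lymphocytes, and 3, 4 and 3 when adjusted over the list alone. miR-125a-5p did not pass against organ macrophages (0.21) or lymphocytes, and its call against monocytes (1.59 ± 0.50; limma adjusted p = 0.0263) ended under each other scaling and without any of the 4 monocyte samples (1.58 without spleen Ly6C-low, 1.57 without bone marrow Ly6C-low, 1.56 without spleen Ly6C-high and 1.65 without bone marrow Ly6C-high cells). Among 9 myeloid miRNAs tested, limma called 0, 1 and 2 higher and 1, 2 and 2 lower in that order (0, 2 and 2 and 1, 3 and 2 at an unadjusted p under 0.05), and against monocytes 2 were higher and 3 lower when adjusted over the list alone. Of 9 lymphoid miRNAs, 4 were higher and miR-150 lower against organ macrophages, and 2 were lower against monocytes and 2 against lymphocytes. The 4 were miR-29a (1.92), miR-29b (1.85), miR-16 (1.79) and miR-181a (1.62), and none of the 4 was called with equal upper quartiles or the median of ratios. The calls on miR-29b and on miR-150 (-1.45) also ended without cortex or brain microglia (miR-29b at most 1.56 and miR-150 -1.39 and -1.35), and that on miR-181a without either of these (1.39 and 1.43), muscle macrophages (1.48) or gut macrophages (1.39).

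Of 8 let-7 members, let-7g and let-7d (-1.60; -1.52 without B cells and -1.45 without CD3/CD4 T cells, where the call ended) were lower against lymphocytes and 0 passed elsewhere in limma (1 higher against monocytes at an unadjusted p under 0.05). Of 5 miRNAs of the miR-17 family clusters, miR-25 and miR-19a were lower against monocytes (-2.52 and -1.44) and lymphocytes (-1.91 and -1.19), where the call on miR-19a ended without bone marrow Ly6C-low (-1.31) or Ly6C-high cells (-1.31) and without B cells (-0.94), CD3/CD4 T cells (-1.27), eye microglia (-1.02), cerebellum microglia (-1.04) or olfactory bulb microglia (-1.11). The endothelial list of 3 had miR-126-3p lower against organ macrophages and miR-10a lower against monocytes (-1.43; -1.11 without bone marrow Ly6C-low cells, where the call ended). miR-148a, the liver list's only member tested, was -0.92 against organ macrophages without passing and lower against monocytes (-3.21) and lymphocytes (-1.39). The kidney and gut list of 3 and the lung list of 4 shared miR-200b, higher against monocytes (1.56) and lymphocytes (1.54), and the lung list also had miR-205 higher against lymphocytes (1.18). All 3 calls ended without eye microglia (1.25, 1.23 and 1.00). Those on miR-200b also ended with equal upper quartiles (0.99 and 0.58), without bone marrow Ly6C-low (1.38), spleen Ly6C-low (1.52) or bone marrow Ly6C-high cells (1.58), cerebellum (1.46) or olfactory bulb microglia (1.41) against monocytes, and without B cells (1.42) or CD3/CD4 T cells (1.45) against lymphocytes. miR-205 was no longer called without B cells (1.17) or CD3/CD4 T cells (1.14). miR-29a was the only member of the astrocyte list tested, and miR-338-3p of the oligodendrocyte list was higher against lymphocytes (limma adjusted p = 0.025), with its call lost without B cells (1.02), regulatory T cells (1.02) or CD3/CD4 T cells. The neuron list of 2 had 0 calls in limma, 1 higher against lymphocytes at an unadjusted p under 0.05 and 1 when adjusted over the list alone. The muscle and heart list of 1 had 0 calls in limma and 0 at an unadjusted p under 0.05. The retina list had 0 members tested, and the erythroid list of 2 had miR-16 higher against organ macrophages and 1 more lower when adjusted over the list alone.

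Across the 24 samples of the miRNA immune set, 0 of 566 miRNAs had every microglia sample above, or every microglia sample below, every other sample, where chance gives 0.00164. Among single sources, spinal cord microglia had miR-223 at 132 (2.89 log2 units above the median of the 7 sources), and cortex and brain microglia had miR-29a (2.30 and 2.09) and miR-125b-5p (1.84 and 2.28) above it. Cortex and brain were also the deepest microglia samples (15643 and 32277 counts, against 2555 to 8452 in the others), so source and depth cannot be told apart there. miR-29b was lowest in eye and cerebellum microglia, but at 3 counts each, the floor of these samples, so no size is given.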

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

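The tests of the 3 patterns weighed here were all chosen after the results they measure had been seen, whereas the comparison with other splits of the samples was set out in advance. Within groups of 4 to 7 samples, 25 of 396 sets of values (6.31%) held a sample far from the rest, judged by its gap to the nearest sample as a share of the whole range on the log2 scale. Chance alone picks out about 1 in 20.

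Among the 7 microglia samples, eye microglia were lowest in the receptor gene Csf1r (3704, nearest 7554, share 0.575), the complement receptor gene C3ar1 (706, nearest 1138, 0.625) and Slc1a3 (150.5, nearest 403, 0.679). Cerebellum microglia were lowest in Ahcyl1 (50.3, nearest 154, 0.625) and highest in Pgk1 (352, nearest 136, 0.627). Olfactory bulb microglia were lowest in Gnas (103, nearest 324, 0.641) and brain microglia in Hprt1 (143, nearest 359, 0.621). A single count was worth 50.4 in cerebellum and 103 in olfactory bulb microglia, so that the lowest values of Ahcyl1 and Gnas rest on 1 count each.

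Among organ macrophages, red pulp macrophages were lowest in Fos (111, nearest 1128, 0.643), Gas7 (64.4, nearest 245, 0.716) and Fcrls (12.8, nearest 123, 0.677) and highest in Abi1 (640.0, nearest 343, 0.606). Heart macrophages were highest in the chemokine gene Ccl2 (315, nearest 64.0, 0.662). Gut macrophages were lowest in let-7g (15.4 or 2 counts, under the floor of 3; nearest 129, 0.574) and liver macrophages in miR-16 (51.2, nearest 157, 0.623). Among monocytes, spleen Ly6C-low cells were highest in Fos (8952, nearest 2155, 0.854) and bone marrow Ly6C-low cells in Pgk1 (742, nearest 296, 0.946).

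Among lymphocytes, B cells were highest in the B-cell adaptor gene Blnk (2937, nearest 47.7, 0.871), in Apoe (801, nearest 30.7, 0.945) and in miR-142-3p (1005, nearest 437, 0.838). NK cells were highest in Gas7 (346, nearest 14.4, 0.874), Fcrls (108, nearest 7.18, 0.842), Trem2 (35.9, nearest 3.26, 0.923), Tmem119 (24.2, nearest 3.26, 0.901) and Il1a (11.7, nearest 3.26, 0.907). A single count was worth 11.9 in NK cells, so that the values of Trem2, Tmem119 and Il1a are 3, 2 and 1 counts and do not show expression. CD3/CD4 T cells were highest in miR-1949 (4.55, nearest 2.19, 0.848).

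In the mRNA immune set most genes called against organ macrophages were higher in microglia (204 of 216). Counts scaled up in the samples known to be shallow are argued against, since 92.0% of the calls were still higher without the 4 samples of the fitted groups in which 1 count was worth over 20 units. The depth of samples without recovered counts is unknown, however. The scaling to 6 reference genes may account for part of the shift. With Gusb alone as the scaler the panel median was -0.58 and with Hprt1 -0.07, against 0.72 with Gapdh, 1.77 with Cltc, 1.67 with Pgk1 and 3.68 with Tubb5. A true difference between the cell types stays open as well. The panel genes may have been chosen from the array results, so the share of higher genes is not independent evidence of such a difference.

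Of 7 immediate early genes, 4 passed as higher in microglia against organ macrophages (median of the 7 1.77, lowest -0.052) and 6 against monocytes (median 3.91), and Fos turned to -0.69 against organ macrophages with equal totals. Tissue dissociation shared by the organ preparations stays open. Organ macrophages stood 2.12 above monocytes, panel shift included (panel median in microglia 1.12 and 2.56 above them). That shift stays open too, with the list's median at the 63.75th percentile of the panel genes. Sources differed, from 3.24 above the organ macrophage mean in hippocampus and 3.20 in cortex to 0.04 in eye and -1.07 in brain microglia. A difference between regions was not tested (1 sample each). The brain sample may have been processed apart (reference gene Cltc 2816 against 243 to 925 in the 6 others).

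In CNS-set oligodendrocytes, 12 genes at 1000 or more in microglia lay at a median of 2.22% of that level (at most 4.47%, for Tgfbr1). They were chosen for lying under 2% of it in astrocytes and neurons. A background shared by all samples without microglia is argued against. The oligodendrocyte mean was a median of 3.46 times the highest mean of astrocytes and neurons (over 2 times in 10). This covers all 14 homeostatic genes at 1000 or more in microglia. RNA of microglia in these samples may account for the 12 (interquartile range of log2 ratios 0.38). Egr1 and Fos, outside the 12, held smaller shares (values above), unlike a constant carry-over. No biological explanation was tested.

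Other splits of the same samples were compared with the real one. On the array the 10 splits are too few for a share under 0.05, with 3115 calls in the real split and 0 as the highest other. In the mRNA immune set only 1 of 100 splits, the real one, gave as many calls against organ macrophages (216, highest other 170), monocytes (306, highest other 281) and lymphocytes (275, highest other 214). These shares are under 0.05, though 100 splits cannot show a share below 1 in 100. In the miRNA immune set the share was also under 0.05 against monocytes (2 of 100 splits, 20 calls, highest other 32) and lymphocytes (2 of 100, 28 calls, highest other 48). In both, another split gave more calls than the real one, so chance is not excluded. Against organ macrophages the share was not under 0.05 (5 of 100, 15 calls, highest other 23).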

How the results depend on the processing

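The scaling to 4 reference genes, common floor, edgeR, omission of shallow samples and viral probe limit were chosen after seeing the data, the other settings before. Of 14473 values of named genes under other settings, 13645 stayed on their side of the threshold, 708 lost the call, 88 gained it and 32 changed sign with a call under at least 1 of the settings. Of the 13645, 67 (26 genes and comparisons) changed sign but were called under neither setting, such as Apoe against monocytes with 4 reference genes (-0.50). Of 558 counts, 457 stayed within 1.5 times the reported one. Those of the array and each mRNA CNS comparison did so under every scaling and sample left out. A count adds higher and lower calls and hides turns in their balance. For mRNA these arose with equal totals or upper quartiles against neurons and organ macrophages and with the median of ratios against monocytes and lymphocytes. A turn for miRNA arose against lymphocytes, as with equal totals. The listed housekeeping genes changed nothing, being the scalers already. Not run, lacking array gene names, were 1 cluster per symbol and the settings of the array lists and the array-panel comparison. Where a single sample was left in a group, it is assumed to vary like the other groups. Replicate numbers did not pair the samples, with residual correlations of -0.01 to 0.03 on the array, -0.20 to 0.09 in the mRNA and -0.25 to 0.08 in the miRNA CNS set. Replicate blocks gave 3121 calls on the array and 7 against hippocampal neurons for miRNA. Depth limited single counts, worth up to 103 units for mRNA and 8.53 for miRNA.

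Without a fold minimum the array gave 8517 calls, since a criterion was dropped. In the mRNA CNS set 81 genes were higher than in every group with equal totals and 88 with equal upper quartiles, and the cause was not tested. Part of the excess over independent lists may come from the microglia samples that all comparisons share.

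Against monocytes the mRNA immune set gave 173 calls with equal totals, 184 with equal upper quartiles and 180 with the median of ratios, and the cause was not tested. With the common floor 85, 86 and 83 genes were called against organ macrophages, monocytes and lymphocytes, with only 197 genes tested. edgeR, on the samples with recovered counts only, called 88 against organ macrophages, and the cause was not tested. Complete separation held for 13 genes with equal totals, 28 with equal upper quartiles, 18 with the median of ratios and 48 with 4 reference genes (cause not tested), and for 45 with a required margin of 1 log2 unit.

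The 32 sign changes that involved a call arose in the mRNA immune set under 3 scalings, and the cause was not tested. With equal totals Tgfbr2 (-0.47), Tgfb1 (-1.32), Cd86 (-1.62), Fos (-0.69), Gusb (-0.40) and Hprt1 (-0.99) reversed against organ macrophages, Tgfbr2 (-0.035), Cd86 (-0.77), Apoe (-2.43) and Gusb (-0.13) against monocytes, and Cd86 (-0.088), Gusb (-0.14) and Hprt1 (-0.82) against lymphocytes. With equal upper quartiles Tgfb1 (-0.60) and Hprt1 (-0.30) reversed against organ macrophages, Tgfbr2 (-0.081), Cd86 (-0.82), Apoe (-2.49) and Gusb (-0.17) against monocytes, and Hprt1 (-0.45) against lymphocytes. With the median of ratios Tgfb1 (-0.38) and Hprt1 (-0.091) reversed against organ macrophages, Tgfbr2 (-0.38), Cd86 (-1.12), Clu (-0.10), Apoe (-2.80), Hprt1 (-0.20) and Gusb (-0.49) against monocytes, and Cd86 (-0.40), Clu (-0.14), Gusb (-0.47) and Hprt1 (-1.16) against lymphocytes.

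In the miRNA CNS set a pseudocount of 1 gave 5 calls against oligodendrocytes and 1 miRNA higher than in every group, the total of the top 100 miRNAs also 1, and the median of ratios 10 calls against cortical neurons. Fits of only 2 groups gave 24 calls against astrocytes, 23 against oligodendrocytes, 33 against cortical neurons, 58 against red pulp macrophages and 0 against hippocampal neurons in limma (12 higher and 8 lower at an unadjusted p under 0.05), so that 0 were higher than in every group. Sample weights gave 23, 31, 34, 58 and 6 in that order. The cause of these changes was not tested.

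In the miRNA immune set a pseudocount of 50 gave 7, 12 and 13 calls against organ macrophages, monocytes and lymphocytes, and the common floor 8, 12 and 13 with 85 miRNAs tested. Without a low filter, with 566 tested, there were 8 against organ macrophages and 11 against monocytes, and with a filter at 100, with 36 tested, 13 against monocytes and 13 against lymphocytes. Equal upper quartiles and the median of ratios each gave 4 against organ macrophages and 13 against monocytes, and the top 100 total 9 and 8. Only 2 groups in the fit gave 9 against organ macrophages, and edgeR 45 against lymphocytes. The cause of these changes was not tested.

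Leaving out each sample in turn gave 3070 to 3160 calls on the array. In the mRNA CNS set it gave 245 to 252 against astrocytes, 255 to 260 against oligodendrocytes, 237 to 256 against cortical and 271 to 274 against hippocampal neurons, and 126 to 145 genes higher than in every group. In the mRNA immune set it gave 209 to 225, 277 to 318 and 244 to 284 against organ macrophages, monocytes and lymphocytes, and 92 to 121 separated genes (121 without eye microglia). In the miRNA CNS set it gave 2 to 19 against astrocytes, 1 to 19 against oligodendrocytes, 2 to 42 against cortical and 3 to 310 against hippocampal neurons (310 without their replicate 2), 1 to 30 against red pulp macrophages and 1 to 4 higher than in every group. In the miRNA immune set it gave 7 to 20 against organ macrophages, 9 to 24 against monocytes (9 without bone marrow Ly6C-low cells) and 13 to 37 against lymphocytes (13 without CD3/CD4 T cells), and 0 to 0 separated miRNAs.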

Other observations

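The values here were picked after they had been seen, and single samples were not tested. The cell types with 1 sample entered no comparison. In the miRNA immune set miR-155 measured 499 in splenic dendritic cells, 467 in neutrophils and 837 in gut macrophages, and had a median of 204 over the 7 microglia samples (48.1 in brain to 397). The means of microglia (205) and organ macrophages (313) did not differ by limma (-0.61; adjusted p = 0.369). miR-34c, listed among lung and epithelial miRNAs, ran from 178 in bone marrow Ly6C-low cells to 11874 in gut macrophages, with 7178 in eye and 10586 in cerebellum microglia. The 3 high samples held few counts (3408, 2647 and 4944) and the bone marrow sample many (70671). Liver macrophages, with the fewest counts (1741), went the other way, since no miRNA there exceeded 572. Depth was not told apart from cell type for this miRNA.

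miR-126-3p, of the endothelial list, measured 751 in lung, 572 in liver and 375 in heart macrophages, 5.14 in spleen macrophages and 0.87 to 7.57 in the 7 microglia samples. Eye microglia also held the autotaxin gene Enpp2 at 752 and the adhesion gene Ncam1 at 243.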
